A study of Arabidopsis thaliana with 24 samples.

How the data were processed

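Root RNA of Arabidopsis thaliana was hybridised to 24 Affymetrix ATH1 arrays, 3 for each combination of 4 genotypes (Col-0, nlp6, nlp7, nlp6nlp7) and 2 times. Per the labels, seedlings spent 9 days in medium with 12.5 mM ammonium succinate and roots were harvested at 0 min or 35 min after 25 mM KNO3 at pH 5.5, with about 200 seedlings in 3 boxes per replicate. The deposited values are intensity values per probe set, given as whole numbers from 1 to 36178 on a linear scale. The authors had scaled them per array: the mean after trimming 2% at each end was 500.1 to 500.5 on every array. The software that summarised probes into probe sets is not given in the sources used here. Array medians lay between 163 and 196, and the share of values at the floor of 1 was 1.08% to 3.54%. Arrays give no read depth, so their number limits the precision.

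Intensities were moved to the log2 scale after adding 26, the 20th percentile of all values. The table holds 22776 probe sets, of which 62 controls were set apart and 22714 were tested without a filter on dim values. Genes were named from the probe table and the gene symbols and order of the TAIR10.1 reference. Of the 22714, 13490 match 1 gene, 503 match several and 8721 match none there. The array table names no genome assembly, so no coordinates are given. No column was left out.

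Groups, comparisons, tests, gene lists, the rule for naming genes and most alternative settings were fixed before the data were examined. One group-means model with limma 3.58.1 in R 4.3.3 covered all 24 arrays with 16 residual degrees of freedom and moderated variances. Each comparison was a two-sided contrast: the response at 35 min against 0 min in each genotype, differences between responses, the departure from additivity, and each mutant against Col-0 at each time. P-values were adjusted by the Benjamini-Hochberg method over the 22714 probe sets, with adjusted p under 0.05 as the threshold. Errors of log2 changes are standard errors from that model.

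The named genes were those with 1 match that passed the threshold: the 10 highest and 10 lowest responses in Col-0 whose 3 arrays at 35 min lay on one side of all 3 at 0 min, the 10 highest and 10 lowest response differences of nlp6nlp7 against Col-0, and the 5 highest and 5 lowest of the other response differences against Col-0 and of each mutant at 0 min. All members of the fixed lists could be named as well. The 25 fixed lists kept 270 members after 1 whose locus and symbol disagreed was dropped, and 38 of the 270 were measured. For 19 members the reference gives no symbol. A further 16 lists were added after the coverage was seen and before contrasts were computed. Lists with at least 3 measured genes were tested with camera in limma at a preset correlation of 0.01, and again with an estimated correlation, adjusted over the lists of a comparison.

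The response retained in each mutant was the median response of probe sets called at 2-fold or more in Col-0, chosen without the Col-0 replicate that measured them, with exact permutation tests between genotypes. Neighbouring genes were scanned for runs with a shared shift over the brighter named genes, with 200 permuted gene orders as reference. Other splits of the arrays were refitted, 10 for comparisons of 3 against 3 arrays and 100 drawn with a fixed seed for response differences. Recovery was tested on simulated data, with 200 changed probe sets in each of 5 runs. In the Col-0 response 43.3%, 77.0% and 98.8% of simulated 1.5-fold, 2-fold and 4-fold changes were recovered, with 6.06% false calls. In a response difference 18.8%, 50.1% and 90.9% were recovered, with 6.68% false calls. A simulated run of 100 genes was recovered with its exact ends.

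Alternatives covered quantile normalization, centring each array on its median, leaving out the dimmest 25% or 50%, trended and robust variances, only the arrays compared, array weights, replicate number as a block, 1 probe set per named gene, pseudocounts of 3 and 103 (the 5th and 40th percentiles), and each array left out in turn. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 served for tables and plots.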

Results

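Transcript levels were measured in Arabidopsis thaliana roots on 24 Affymetrix ATH1 arrays. The 4 genotypes were the reference line Col-0, the single mutants nlp6 and nlp7, and the double mutant nlp6nlp7. NLP6 and NLP7 are NIN-like transcription factors known as regulators of the nitrate response. Seedlings grew with ammonium succinate as nitrogen source, and roots were taken at 0 min and at 35 min after addition of 25 mM KNO3. Each of the 8 groups of genotype and time held 3 biological replicates of about 200 seedlings. The comparisons ask which genes respond to nitrate in Col-0 and how loss of NLP6, NLP7 or both alters that response. No group received a potassium salt without nitrate, so elapsed time, handling and potassium go together with nitrate in every response. The number of arrays limits the precision of each value.

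A gene could be named for 13490 probe sets that match 1 gene each. A further 503 probe sets match several genes, and 8721 of the 22714 tested (38.4%) carry no gene name in the tables used here. NLP6 and NLP7 are among the genes without a named probe set, so the planned comparison of the mutated genes themselves could not be made by name. Among the unnamed probe sets, 261945_at and 254195_at followed the genotype labels, and both were singled out after their values were seen. At 0 min, 261945_at had an intensity of 413 ± 60.1 (SD, n = 3) in Col-0 and 369 ± 15.1 in nlp7. It fell to 17.7 ± 18.9 in nlp6 and 3.33 ± 1.53 in nlp6nlp7 (limma adjusted p = 1.9e-07 and 8.4e-09 against Col-0). The intensity of 254195_at at 0 min was 617 ± 8.39 in Col-0 and 447 ± 83.4 in nlp6. It was 18 in each nlp7 array and 10.7 ± 4.62 in nlp6nlp7 (limma adjusted p = 5.2e-09 and 1.5e-09 against Col-0). All 12 arrays of the lines carrying the nlp6 mutation lay below the other 12 for 261945_at, with a gap of 1.84 on the log2 scale. For 254195_at, all 12 arrays carrying the nlp7 mutation lay below the other 12, with a gap of 2.14. No other probe set parted either set of 12 arrays by 1 or more.

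Time after nitrate separated the arrays most, and the double mutant came next. The first principal component took 29.2% of the variance and placed every 35 min array apart from every 0 min array. The component that took 11.6% placed all 6 nlp6nlp7 arrays apart from the other 18. On the component that took 8.9%, replicate 1 of nlp7 stood apart at both times, at -34.83 and -37.26. Correlations between replicates of a group, taken across probe sets, lay between 0.979 and 0.992.

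**Figure D1:**
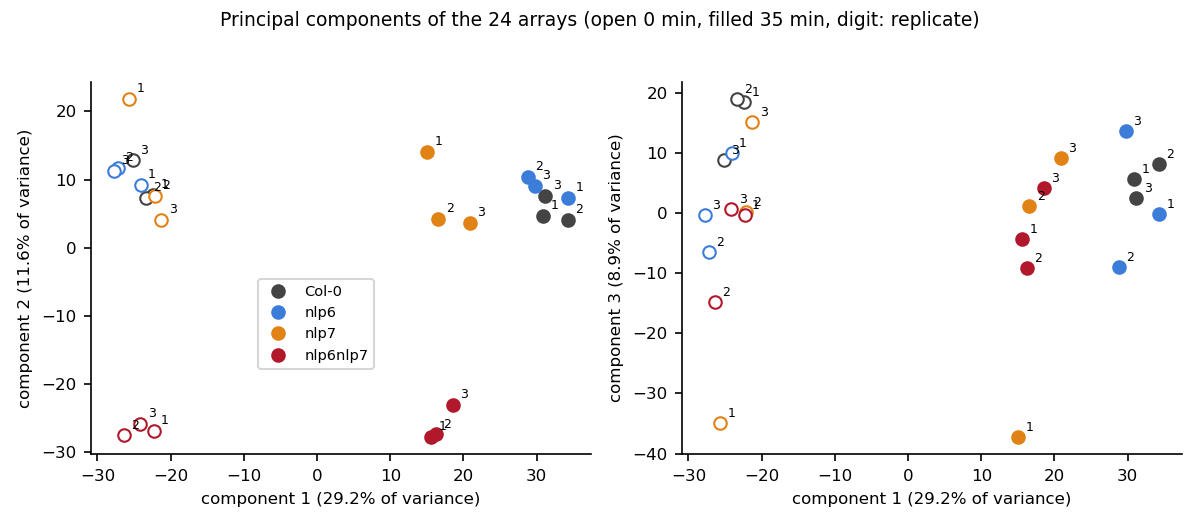
Scores of the 24 arrays on the first 3 principal components of the log2 intensities, in arbitrary units, with the share of variance on each axis; open circles are 0 min, filled circles 35 min, colours are genotypes and digits are replicates. The left panel shows nlp6nlp7 apart from the other genotypes, and the right panel shows replicate 1 of nlp7 apart at both times.

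In Col-0 roots after nitrate, AT5G10210 (log2 change 5.37) and AT3G07350 (5.23) rose most among named genes. PGM (AT1G78050), annotated as a phosphoglycerate mutase, had intensities of 288 and 11500 and rose 36.9-fold on intensity plus 26, the scale of every fold value here (5.20 ± 0.14 SE, n = 3 per time, limma adjusted p = 1.6e-15). AT1G80380, the glycerate kinase gene, rose 33.2-fold (5.06 ± 0.20, adjusted p = 4.1e-13). AT2G48080 (4.87), AT4G32950 (4.42), AT5G54170 (4.30), AT1G49500 (4.05), the kinase gene WNK7 (3.66) and AT3G28510 (3.60) completed the 10 highest. The deepest falls with 26 added were those of AT3G14200 (log2 change -3.08 ± 0.28), the cytochrome P450 gene CYP718 (-2.97), AT4G17670 (-2.83), AT5G67430 (-2.80) and AT1G64590 (-2.52). ARL, an ARGOS-like gene (-2.32), the GRAS family gene AT3G13840 (-2.29), AT1G33055 (-2.22), AT1G26800 (-2.15) and SUFE2 (-2.14), which serves iron-sulfur cluster assembly, followed. For these 20 genes all 3 arrays at 35 min lay on one side of all 3 at 0 min, and each call held under every alternative tried. The sizes and the order of the falls depend on the pseudocount. With 3 and 103 in place of 26, CYP718 had -5.16 and -1.52, AT3G14200 -4.15 and -1.92, and AT5G67430 -4.13 and -1.54. No other of the 20 moved by over 1.5 times, and the standard errors printed here leave this dependence out. In all, 2306 of 22714 probe sets changed, 1056 higher and 1250 lower, of which 419 rose and 214 fell at least 2-fold. The higher share was 45.8% as deposited and 57.3% after centring each array on its median, so the balance of rising and falling probe sets depends on scaling. The most changed probe sets, 265475_at (5.93) and 258487_at (-3.69), singled out after their values were seen, carry no gene name here.

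**Figure D2:**
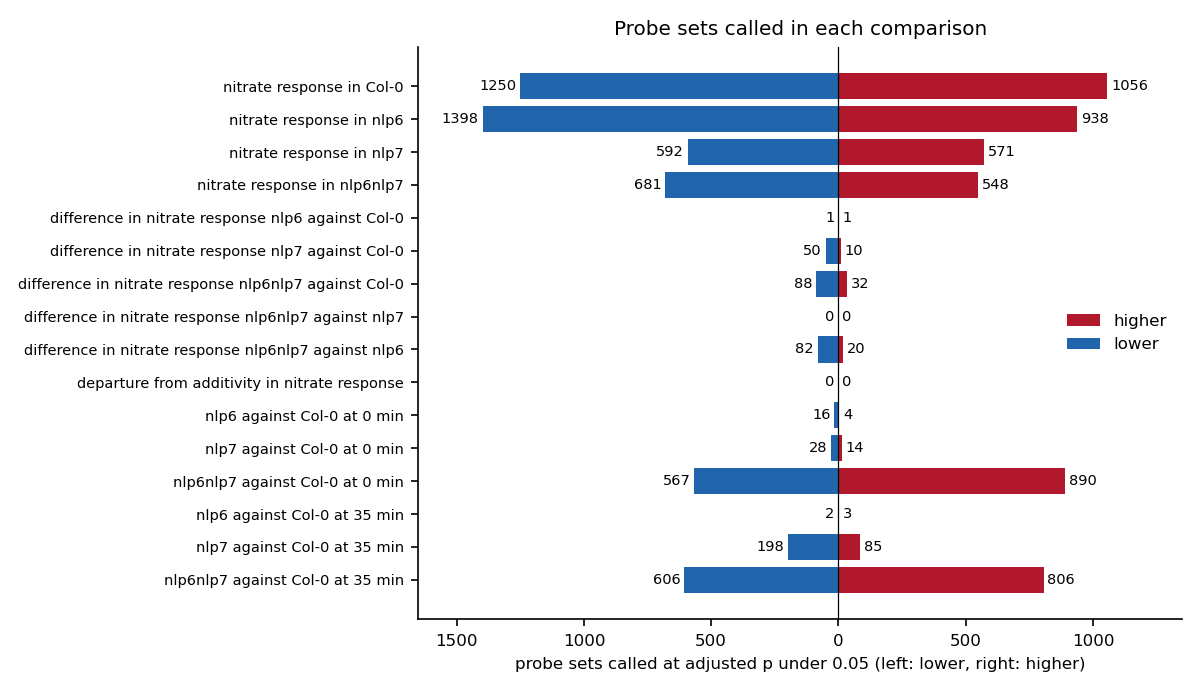
Number of probe sets called at limma adjusted p under 0.05 in each comparison, lower to the left and higher to the right of 0. The nitrate response called 1056 higher and 1250 lower in Col-0 against 548 and 681 in nlp6nlp7, and at 0 min nlp6nlp7 differed from Col-0 in 890 higher and 567 lower.

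The gene lists fixed in advance had 38 measured members, because most well-known nitrate genes have no named probe set here. All 3 measured nitrate-linked transcription regulators, the GARP family genes HHO1, HHO2 and HHO3, rose in Col-0, by 1.96 ± 0.22, 2.01 ± 0.08 and 2.46 ± 0.10 on the log2 scale. As a list they shifted upward (limma camera adjusted p = 1.19e-11, and adjusted p = 3.7e-05 with an estimated correlation). They are 3 of the 18 loci on that list and belong to 1 family, so the list speaks here for these HHO genes alone. Of 7 measured CC-type glutaredoxins, 4 rose, GRXS4 by 2.75 ± 0.30, GRXS8 by 2.03, GRXS3 by 1.82 and GRXS5 by 1.64. CEPD1 (-0.24), CEPD2 (0.39) and GRXS1 (-0.04) did not pass the test. The glutaredoxin list shifted upward with adjusted p = 2.12e-05, and with adjusted p = 0.0214 with an estimated correlation. The 4 risen members are close tandem paralogs. Both reductant supply genes, the 6-phosphogluconate dehydrogenase genes PGD1 and PGD3, rose by 2.33 ± 0.09 and 3.04 ± 0.12. The hypoxia gene HRA1 fell by 1.41, the stress gene WRKY53 fell by 0.80, the clock gene GI fell by 0.72 and the auxin-conjugating gene GH3.5 fell by 0.92. The other 5 measured genes of early auxin response passed no test over all probe sets, and their list had camera adjusted p = 0.376.

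Adjusted over the list alone, the counts were 3 of 3 regulators higher, 4 of 7 glutaredoxins higher and 2 of 2 reductant supply genes higher, equal to those over all probe sets. The nitrate transporter gene NRT2.5, at -0.57 ± 0.24, passed adjusted over the list alone, where it was the 1 member, and not over all probe sets. PYE, at -0.37 in the iron deficiency list, did likewise while BHLH101 did not. No call was made by limma in Col-0 for NRG2 (-0.03), the cytokinin response genes ARR15 (-0.34) and ARR16 (-0.06), ZAT10 (-0.25), AKINBETA1 (0.09), BRX1-1 (-0.11), or the flavonoid genes DFR (0.14) and UF3GT (-0.24). The shoot markers LHCB4.1 (0.36), RCA (0.08) and PRK (-0.29), the root hair gene EXPA7 (0.03) and the reference genes UBC21 (-0.10) and SAND (-0.07) had no call either, and no gene of these lists beyond NRT2.5 and PYE was added adjusted over the list alone.

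The 16 gene families added once the coverage of the tables was known, before any contrast was computed, did not shift as lists in Col-0, with camera adjusted p of 0.198 or more. Within them, 6 of 47 UDP-glycosyltransferases fell and 1 rose, and 4 of 26 cytochrome P450s fell and 2 rose. Of 15 tetraspanins 4 fell, of 9 xyloglucan transferases 3 fell and 2 rose, and of 17 expansins 3 fell and 2 rose. Among 20 beta-glucosidases 2 rose, among 14 SWEET sugar transporters 2 rose and 1 fell, and among 11 tau glutathione transferases 2 rose and 1 fell. No call was made by limma among 122 cytosolic ribosomal proteins, 64 plastid-encoded genes or 29 serine carboxypeptidase-like genes, whose median log2 changes were -0.04, -0.18 and -0.04. The 22 trichome birefringence-like genes, 40 AGAMOUS-like genes, 7 Aux/IAA genes, 10 RALF-like peptides and 12 ubiquitin-conjugating enzymes had at most 1 call in each direction.

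The median nitrate response was close to that of Col-0 in nlp6 and smaller in nlp7 and nlp6nlp7. Genes induced at least 2-fold in Col-0 rose by a median of 1.51 ± 0.14 (SD, n = 3 pairs of arrays matched by replicate number) on the log2 scale in Col-0 and 1.49 ± 0.08 in nlp6. The same genes had medians of 1.03 ± 0.04 in nlp7 and 0.97 ± 0.07 in nlp6nlp7, which is 68.6% ± 6.88 and 64.5% ± 3.37 of the Col-0 response. Genes lowered at least 2-fold in Col-0 had medians of -1.19 ± 0.06 in Col-0, -1.15 ± 0.06 in nlp6, -0.87 ± 0.08 in nlp7 and -0.83 ± 0.08 in nlp6nlp7. Their retained shares were 96.6% ± 1.19, 73.7% ± 10.2 and 69.7% ± 7.95. Genes were chosen without the Col-0 replicate that measured them, giving 373 to 417 induced and 206 to 219 lowered probe sets per choice. Exact two-sided permutation tests gave p = 0.9 for nlp6 and p = 0.1 for nlp7 and nlp6nlp7 among induced genes, and p = 0.5, 0.1 and 0.1 among lowered genes. With 3 values against 3, 0.1 is the smallest p this test can give, so it cannot pass 0.05. The SDs rest on matching arrays by number, which the labels do not ask for. Over all 216 matchings, an alternative chosen after seeing the data, the retained share of induced genes lay between 67.3% and 70.9% in nlp7 and between 63.1% and 67.1% in nlp6nlp7, and its SD between 0.141 and 12.1 and between 0.265 and 7.04.

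**Figure D3:**
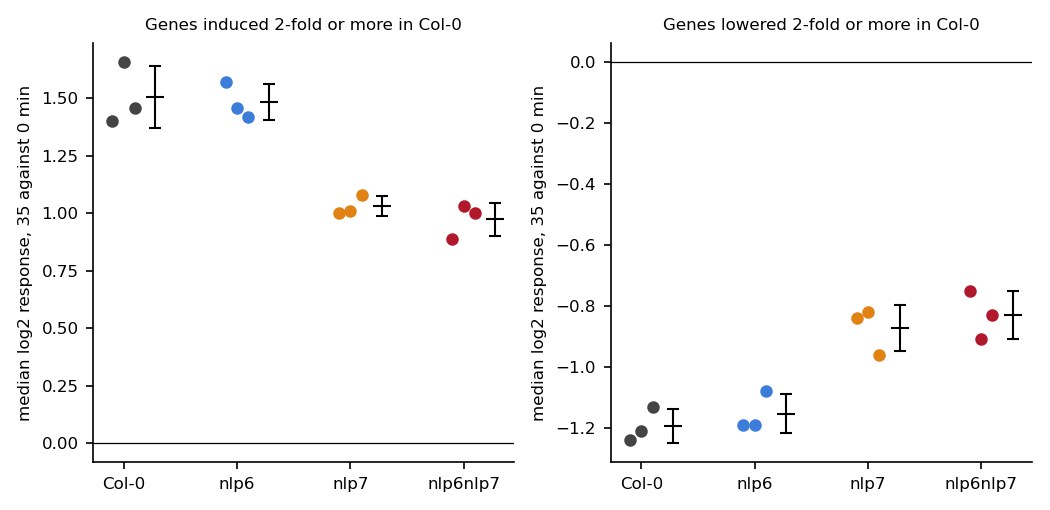
Median log2 response (35 min against 0 min) of the probe sets that changed at least 2-fold in Col-0, induced on the left and lowered on the right; each point is 1 array at 35 min against the array at 0 min with the same replicate number, and bars are mean and SD (n = 3). Values of nlp7 and nlp6nlp7 lie nearer 0 than those of Col-0 and nlp6 in both panels.

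Most induced genes were still called in each mutant. Of 419 probe sets induced at least 2-fold in Col-0, 375 (89.5%) were also called higher in nlp6, 317 (75.7%) in nlp7 and 292 (69.7%) in nlp6nlp7. Of 214 lowered, 198, 170 and 153 were shared. In nlp6 the response called 2336 probe sets, 938 higher and 1398 lower. The count was 1163 in nlp7, 571 higher and 592 lower, and 1229 in nlp6nlp7, 548 higher and 681 lower. The higher share moved from 40.2% to 58.9% in nlp6 and from 44.6% to 64.9% in nlp6nlp7 after centring each array. A fit of only the arrays compared called 408 in nlp7 and 1230 in nlp6, and array weights called 2082 in nlp6nlp7. The Col-0 count moved with the settings too. Apart from single arrays left out, it ran from 1118 to 3253, and that of nlp6nlp7 from 596 to 2082. HHO1, HHO2 and HHO3 rose in nlp6 (list median 2.19) and nlp7 (1.70), and HHO2 and HHO3 rose in nlp6nlp7 (2.05 and 2.09). The regulator list passed camera in all 3 mutants with an estimated correlation, at adjusted p of 6.6e-05 or less. GRXS3, GRXS4, GRXS5 and GRXS8 rose in every mutant. Their list kept its call with an estimated correlation in nlp7 (adjusted p = 0.04) and lost it in nlp6 (adjusted p = 0.0924) and nlp6nlp7 (adjusted p = 0.112).

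In nlp7 roots, a small set of genes passed the test of a weaker induction than in Col-0. The median over all induced genes was smaller too. A response difference recovered 18.8% of simulated 1.5-fold changes, so many weaker responses may go uncalled. The glycerate kinase gene AT1G80380 rose by 5.06 on the log2 scale in Col-0 and 2.47 in nlp7, a difference of -2.59 ± 0.29 (SE, limma adjusted p = 0.00028). AT5G26200, a mitochondrial carrier family gene, rose by 2.66 in Col-0 and by 0.80 in nlp7 (difference -1.86 ± 0.20, adjusted p = 0.00026). AT5G53750 rose by 2.34 in Col-0 against -0.14 in nlp7 (difference -2.48). AT5G52050, known as the efflux carrier gene DTX50, differed by -1.95 and AT5G54170 by -1.42. Less lowered in nlp7 were AT4G17670 (difference 1.13), AT4G23870 (0.89) and AT2G19310 (0.88), while AT1G11700 (1.04) and AT3G16990 (0.80) had responses of 0.10 and 0.36 in nlp7 against -0.94 and -0.43 in Col-0. The 3 regulators HHO1, HHO2 and HHO3 had differences of -0.81, -0.31 and -0.62, none called over all probe sets and 3 of 3 lower adjusted over the list alone. Their list passed camera (adjusted p = 9.92e-05, and adjusted p = 0.00576 with an estimated correlation).

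Across the array, 60 probe sets responded differently in nlp7, 50 with a lower and 10 with a higher value than in Col-0. Of the 419 induced at least 2-fold in Col-0, 42 (10%) rose significantly less in nlp7 and 0 in nlp6. The 419 were chosen on the same Col-0 arrays that enter the difference, which favours a smaller response in a mutant. The count of 60 was 30, 30 and 39 without replicates 1, 2 and 3 of Col-0 at 0 min, 35 and 28 without replicates 1 and 2 of Col-0 at 35 min, 32 and 39 without replicates 1 and 2 of nlp7 at 0 min, 39 and 33 without replicates 1 and 2 of nlp7 at 35 min, and 9 with only the arrays compared. It was 26 without replicate 1 of nlp7 at both times and 22 with a replicate block within genotype, both chosen after seeing the data. Of the 10 genes named, AT1G80380 and AT5G26200 kept their calls under every alternative, AT5G53750 lost its call in 1 of 25, and the others lost theirs in 6 to 18. With pseudocounts of 3 and 103 the difference of AT5G26200 was -2.34 and -1.05, and that of AT5G52050 -2.63 and -1.24.

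In the double mutant, several strongly induced genes no longer passed the test of a nitrate response at all. AT5G01740 rose by 3.23 in Col-0 and changed by 0.05 in nlp6nlp7 (difference -3.18 ± 0.35 SE, limma adjusted p = 5.3e-05). AT5G26200 went from 2.66 to 0.14 (difference -2.52 ± 0.20, adjusted p = 5.3e-07) and AT5G53750 from 2.34 to 0.15 (-2.19 ± 0.36). HHO1 rose by 1.96 in Col-0 and changed by 0.34 in nlp6nlp7 (-1.62 ± 0.32, adjusted p = 0.017), and AT5G52790 went from 1.75 to -0.08 (-1.83). AT1G80380 still rose, by 1.37 against 5.06 in Col-0, the widest named gap (-3.68 ± 0.29, adjusted p = 5.3e-07). AT5G52050 (-1.84), AT5G28610 (-1.51), AT1G49000 (-1.51) and AT1G73920 (-1.50) also rose less. Other induced genes kept a strong response, among them PGM (4.53 in nlp6nlp7, difference adjusted p = 0.25), PGD3 (2.96, adjusted p = 0.96), PGD1 (2.15, adjusted p = 0.78) and HHO2 (2.05, adjusted p = 0.96). These 4 p-values do not show that their responses were equal. The sizes depend on the pseudocount for AT5G26200, at -4.19 and -1.27 with 3 and 103, for AT5G52790 (-2.43 and -1.05) and for HHO1 (-2.12 and -0.92).

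The genes with a higher response in nlp6nlp7 than in Col-0 were mostly ones that nitrate lowers. AT3G14200 fell by 3.08 in Col-0 and had a change of -0.73 in nlp6nlp7 (difference 2.35 ± 0.40, limma adjusted p = 0.0048). AT2G19310 (difference 1.22), AT1G53180 (1.12) and AT3G13840 (1.02) fell less, and AT5G25280 (0.97), AT1G76210 (1.03) and AT1G11700 (1.02) had no called fall in nlp6nlp7. AT2G47560 rose by 1.73 in nlp6nlp7 with 0.24 in Col-0 (1.49), AT3G13175 rose by 0.89 with -0.27 in Col-0 (1.17), and the dim gene AT4G08420 had a difference of 1.03. In all 120 probe sets responded differently, 32 higher and 88 lower, and of the 419 induced at least 2-fold in Col-0, 71 (16.9%) rose significantly less. That share also rests on probe sets chosen on the same Col-0 arrays, which favours a smaller response in the mutant. The count of 120 was 70 without replicate 2 of nlp6nlp7 at 0 min, 75 without replicate 2 of Col-0 at 35 min and 278 with array weights. Of the 20 genes named, HHO1 lost its call in 8 of 24 alternatives, AT4G08420 and AT1G76210 in 14 of 23, AT3G13175 in 7 of 25, AT1G11700 and AT5G52050 in 6, AT5G25280 in 3, AT1G49000 in 2, and AT3G14200 in 1. With pseudocounts of 3 and 103 the differences were 3.33 and 1.39 for AT3G14200, 2.74 and 0.35 for AT4G08420, and 2.67 and 0.36 for AT1G76210.

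**Figure D4:**
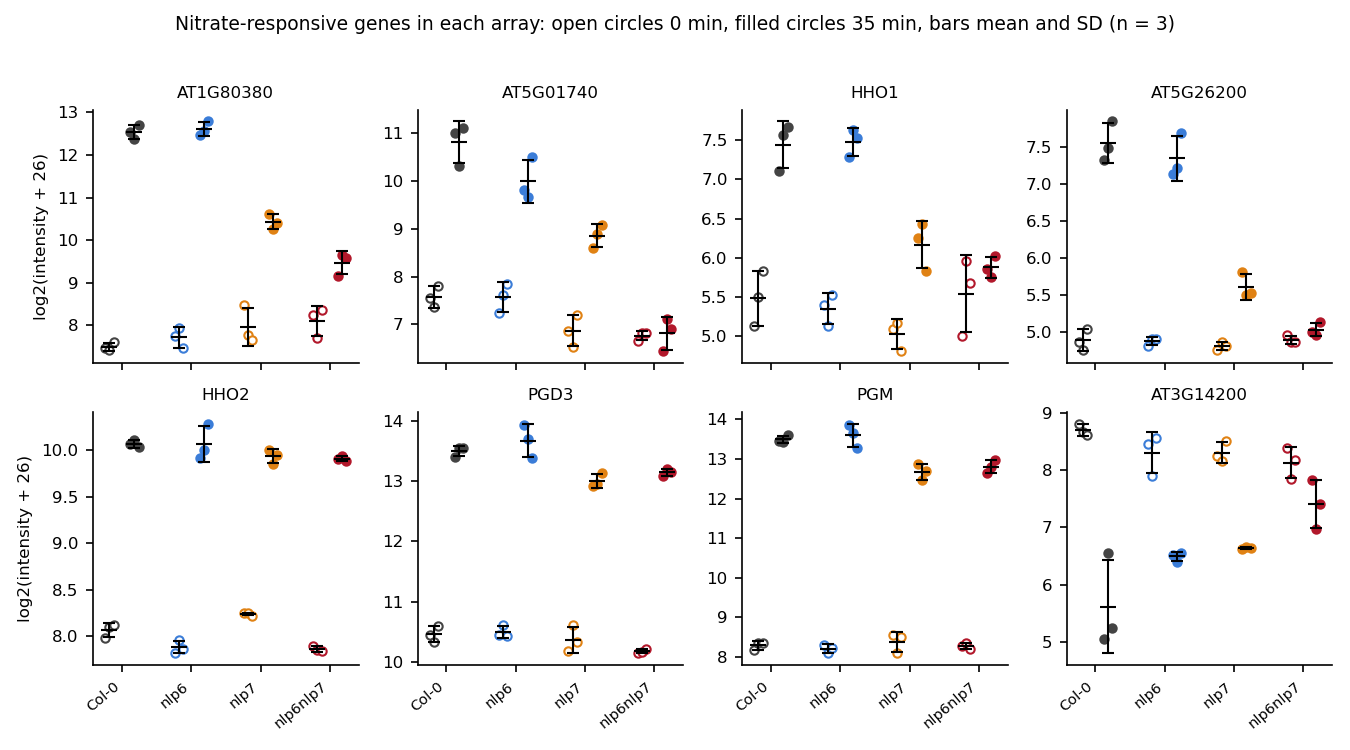
Log2 of intensity plus 26 for 8 genes in each array, open circles at 0 min and filled circles at 35 min, with bars for mean and SD (n = 3). In nlp6nlp7 the 35 min values of AT5G01740, AT5G26200 and HHO1 lie close to their 0 min values, while those of HHO2, PGD3 and PGM lie far above them.

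The list of nitrate-linked regulators had 1 of 3 members lower in its response in nlp6nlp7 over all probe sets and 2 of 3 lower adjusted over the list alone, with camera adjusted p = 0.021 and adjusted p = 0.187 with an estimated correlation. The glutaredoxins had differences of -1.49 for GRXS4, -0.71 for GRXS8, -0.62 for GRXS3 and -0.09 for GRXS5, none called over all probe sets and 1 adjusted over the list alone, at camera adjusted p = 0.021 and adjusted p = 0.423 with an estimated correlation. The small shifts of the ribosomal proteins (median 0.14) and beta-glucosidases (-0.22) had adjusted p = 0.803 and 0.505 with an estimated correlation.

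Weaker responses in nlp7 and nlp6nlp7 fell on many shared probe sets. Of the 50 lower in nlp7 and the 88 lower in nlp6nlp7, 41 were the same, against 0.194 for independent choices. Of the 10 and 32 higher, 8 were shared, against 0.0141. Simulated arrays with a shared Col-0 and no true difference gave 0 shared probe sets in 20 simulations, which says little because at most 2 were called in either comparison. Over all 22714 probe sets the covariance of the 2 response differences was 0.0548, against a mean of 0.0389 in those simulations. Over 381 probe sets induced in nlp6, the response difference of nlp7 against nlp6 and that of nlp6nlp7 against Col-0, which share no arrays, correlated at 0.43. With Col-0 as reference for both, the correlation was 0.79. A weakening that grows with the strength of response would also give such a correlation. Part of the excess of shared calls may still come from the Col-0 arrays that both comparisons use.

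No gene passed the test of a different response between nlp6nlp7 and nlp7. The count was 0 by limma, with 782 probe sets at unadjusted p under 0.05, and it was 1 with a replicate block, 2 without the dimmest 50% or with the larger pseudocount, and 4 with a trended robust variance. The values of AT5G01740 were 1.98 in nlp7 and 0.05 in nlp6nlp7, and those of HHO1 were 1.15 and 0.34. The departure from additivity of both mutations likewise had 0 calls by limma, with 687 at unadjusted p under 0.05, and 0 in every alternative except 1 without replicate 3 of nlp6nlp7 at 0 min. Both 782 and 687 lie below the share of 0.05 of 22714 expected with no true difference. The 0 calls show neither equal responses nor additivity. A response difference recovered 50.1% of simulated 2-fold changes, and recovery was not simulated for additivity. Against nlp6, the double mutant responded differently in 102 probe sets, 20 higher and 82 lower. With only the arrays compared, 58 were called. The regulator list, in which HHO1 was the called member, was lower against nlp6 (median -0.32, camera adjusted p = 4.97e-04, and adjusted p = 0.0206 with an estimated correlation).

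The nlp6 response differed from that of Col-0 in AT4G08420 (difference 1.37 ± 0.21 SE) and AT1G77270 (-1.26 ± 0.20), both at limma adjusted p = 0.042. Both genes are dim in Col-0 at 0 min, with intensities of 20.0 and 6.33, and lost their calls in 19 and 20 of 22 alternatives. Their sizes are set largely by the pseudocount: with 3 and 103 they were 3.22 and 0.49 for AT4G08420 and -3.07 and -0.43 for AT1G77270. No other probe set was called, while 1141 had unadjusted p under 0.05. AT1G80380 rose by 4.89 in nlp6 against 5.06 in Col-0, and HHO1 by 2.13 against 1.96. The count was 0 or 1 without any 1 of the 12 arrays of Col-0 and nlp6, 1 after quantile normalization and 0 in 9 further settings.

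Before nitrate, few probe sets differed between the single mutants and Col-0. In nlp6 at 0 min, AT2G07450 (0.78), AT1G33580 (0.76), AT1G06930 (0.67) and AT5G48060 (0.60) were higher. AT3G19370 (-0.95), AT5G08250 (-0.84), AT5G40340 (-0.80), AT2G17050 (-0.79) and AT2G38800 (-0.68) were lower. These are among 20 probe sets called by limma, 4 higher and 16 lower. In nlp7, 42 were called, 14 higher and 28 lower, with AT2G16190 (1.34), AT3G57020 (1.05), AT2G25450 (0.93), AT5G57655 (0.84) and AT1G54740 (0.80) higher. AT5G64550 (-1.02), AT3G29410 (-0.98), AT1G53340 (-0.87), AT3G13840 (-0.83) and AT3G32040 (-0.81) were lower in nlp7. The nlp6 count was 2, 3 and 37 without replicates 1, 2 and 3 of Col-0 and 49, 5 and 7 without those of nlp6. The nlp7 count was 16, 10 and 8 without replicates 1, 2 and 3 of Col-0 and 12, 16 and 119 without those of nlp7, and it was 11 without replicate 1 of nlp7 at both times. Under other settings the nlp6 count lay between 0 and 110 and the nlp7 count between 1 and 83, and each gene named lost its call in 1 to 10 alternatives. Of their sizes, 7 moved by over 1.5 times with the pseudocount, AT2G07450 most, from 1.79 with 3 to 0.28 with 103.

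After nitrate, nlp6 differed from Col-0 in 5 probe sets and nlp7 in 283. AT4G08420 was 1.01 higher in nlp6 at 35 min, and the unnamed 261945_at was the lowest at -2.27. In nlp7 at 35 min, 85 were higher and 198 lower, and the higher share was 30% as deposited and 18% after centring. The regulator list was lower in nlp7 at 35 min, with 2 of 3 members called and a median of -0.55 (camera adjusted p = 2.88e-05, and adjusted p = 0.00342 with an estimated correlation). The nlp7 count was 164, 114 and 172 without replicates 1, 2 and 3 of Col-0, 178 and 125 without replicates 1 and 2 of nlp7, and 25 to 582 under other settings. The nlp6 count was 1, 1 and 2 without replicates 1, 2 and 3 of Col-0, 62 and 1 without replicates 1 and 2 of nlp6, and 0 to 17 under other settings.

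The double mutant differed widely from Col-0 even before nitrate. AT1G66860 was 5.45-fold higher at 0 min (log2 difference 2.45 ± 0.37 SE, n = 3, limma adjusted p = 0.00027) and AT5G61290 3.15-fold higher. AT1G24320 (3.04-fold), AT1G24030 (2.94-fold) and AT1G23280 (2.85-fold) followed. AT4G33720 was 3.48-fold lower (-1.80 ± 0.43, adjusted p = 0.015), and AT3G55790 (-1.57), AT3G60270 (-1.53), AT5G37450 (-1.41) and the glycosyltransferase gene UGT72E1 (-1.26) were lower too. Among fixed lists, HHO3 (0.64), ZAT10 (0.75) and GI (0.46) were higher and GH3.5 (-0.60) was lower. In all, 890 probe sets were higher and 567 lower at 0 min, and 806 higher and 606 lower at 35 min. At both times 440 were higher, against 31.6 for independent choices, and 161 lower, against 15.1.

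The balance of those calls depends on scaling. The higher share at 0 min was 61.1% as deposited, 51.1% after quantile normalization and 34.2% after centring, and at 35 min it was 57.1%, 50.5% and 41.5%. The 0 min count of 1457 was 967, 923 and 824 without replicates 1, 2 and 3 of Col-0 and 804 and 839 without replicates 2 and 3 of nlp6nlp7, and 2968 with array weights. The 35 min count of 1412 was 913 without replicate 2 of Col-0, 907 without replicate 1 of nlp6nlp7 and 2251 with array weights. Among the names, AT5G61290 lost its call in 1 of 18 alternatives, AT4G33720 in 4, AT3G55790 in 5 and AT3G60270 in 3. AT1G66860 had 2.96 and 1.63 with pseudocounts of 3 and 103.

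Genes in a run on chromosome 1, from AT1G20910 to AT1G27530, were higher together in nlp6nlp7. Gene order was taken from the TAIR10.1 reference; the array table names no assembly. All 155 brighter named genes of the run had higher values than in Col-0 at 0 min and all 155 at 35 min, with medians of 0.83 (1.77-fold) and 0.88 (1.84-fold). Of these, 143 were called higher at 0 min and 138 at 35 min by limma, and 0 were lower in value at either time. The run holds AT1G24320, AT1G24030, AT1G23280 and AT1G26800, named above, and 14 list members. At 0 min and 35 min their differences were 1.26 and 0.94 for UGT85A2, 1.08 and 0.99 for AT1G23410, 0.95 and 0.90 for AT1G27400, 0.68 and 0.67 for UGT74B1, 0.57 and 0.75 for AT1G26880, and 0.46 and 0.67 for GI. HHO3 had 0.64 and 0.27, less at 35 min. The other 7 are dimmer and outside the 155: BGLU40 had 0.44 and 0.68, AGL87 0.37 and 0.35, SWEET1 0.59 and 0.22, UGT85A5 0.01 and 0.02, AGL104 0.37 and -0.06, UGT85A3 0.84 and 0.07, and UGT85A7 0.25 and 1.28. In each nlp6nlp7 array the run stood 0.82 to 0.89 above Col-0, and in the 18 other arrays -0.03 to 0.06. The medians were -0.02 in nlp6 and 0.01 in nlp7 at 0 min. The 20 genes on each side had medians of 0.00 and 0.01, and the nearest neighbours AT1G20890 and AT1G27595 had -0.28 and -0.09.

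The run was found by scanning the brighter named genes after the calls were seen. Its scan statistic was 43.1 at 0 min and 44.6 at 35 min, against at most 7.77 and 7.81 in 200 permuted gene orders. Of the other comparisons scanned, only nlp6 at 35 min also exceeded all its permuted orders, barely (7.32 against at most 7.18). It had 597 genes on chromosome 5 from AT5G24430 to AT5G57480 at a median of -0.03, 44.4% of them higher. The ends of real runs were refined and those of permuted orders were not, so a margin this small cannot be read as a pass. Genes of the chromosome 1 run made up 189 of the 501 named probe sets called higher at 0 min, 178 of 451 at 35 min, and 0 of 305 lower at 0 min. Without the named probe sets of the run, an alternative chosen after seeing the data, 1137 probe sets were called at 0 min and 1162 at 35 min, 621 and 586 of them higher. The nitrate response difference of the run's genes had a median of 0.06, and 119 response differences were called without them against 120 with them. Probe sets with no gene name could not be placed on the chromosome.

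**Figure D5:**
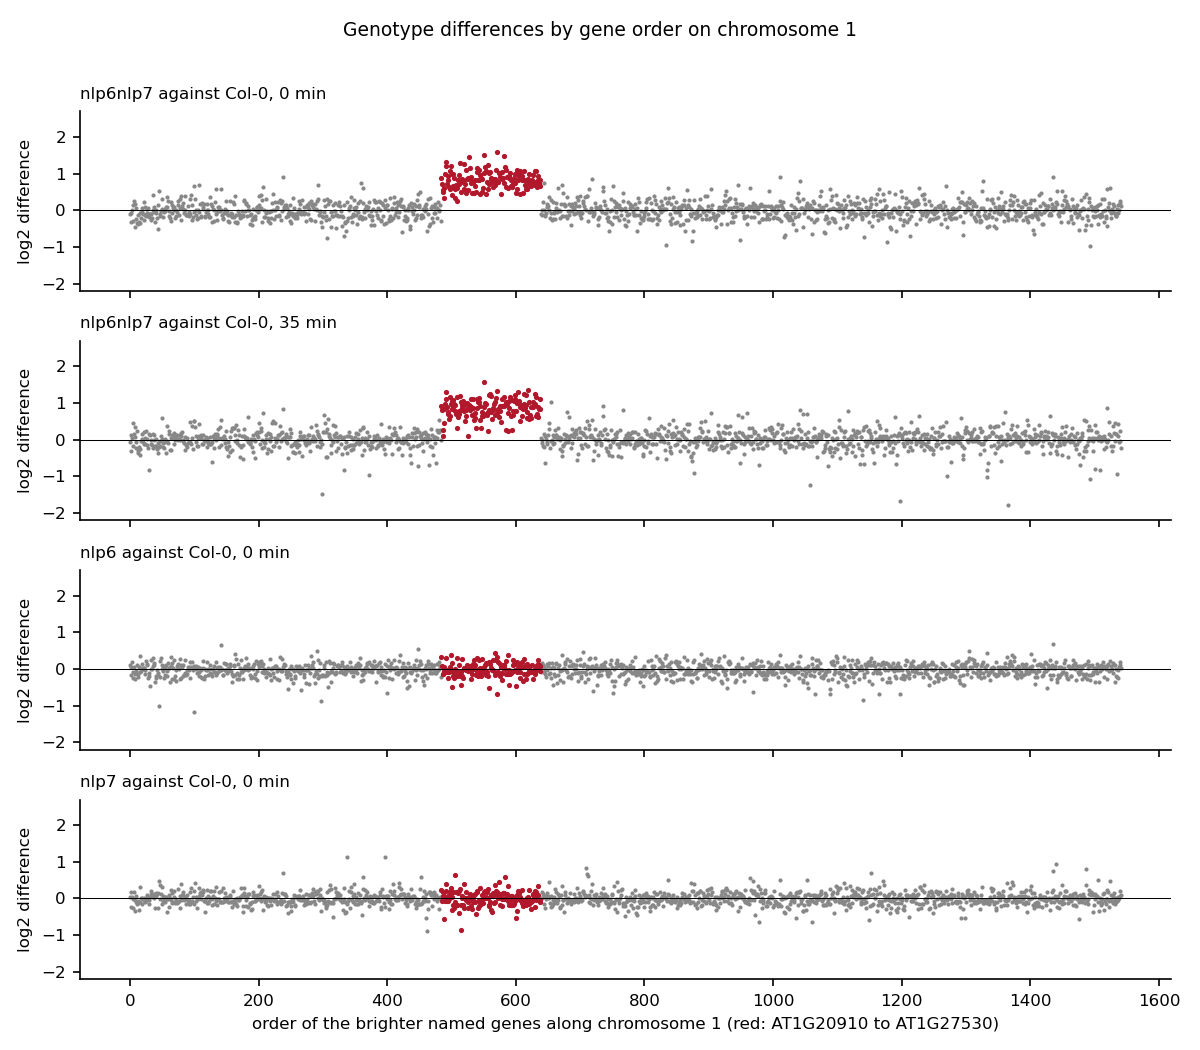
Log2 difference from Col-0 of each brighter named gene in its order along chromosome 1, for nlp6nlp7 at 0 min and 35 min and for nlp6 and nlp7 at 0 min; genes from AT1G20910 to AT1G27530 are red. The 155 red genes all lie above 0 in both nlp6nlp7 panels and are centred near 0 in nlp6 and nlp7.

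RNA quality and tissue makeup were compared between arrays through control probe sets and marker genes. The log2 difference between 3-prime and 5-prime actin probe sets lay between 0.97 and 1.64 in all 24 arrays, and those of GAPDH and ubiquitin between -0.32 and -0.02 and between -0.11 and 0.32. The 5-prime ubiquitin control AFFX-r2-At-Ubq-5_x_at was lower in nlp6nlp7 than in Col-0, by -0.32 at 0 min and -0.36 at 35 min (limma adjusted p = 0.021 and 0.015 over 62 controls), so this control moved with the many calls of nlp6nlp7 against Col-0. The shoot markers LHCB4.1, RCA and PRK and the root hair gene EXPA7 had no call in Col-0 or in nlp6nlp7 at 0 min, where their log2 differences were -0.36, 0.16, 0.06 and 0.03. The 64 plastid-encoded genes had a median of -0.35 in nlp6 at 0 min (camera adjusted p = 1.64e-08, and adjusted p = 0.913 with an estimated correlation).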

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

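The tests of the chromosome 1 run, of the shape of the weaker response, of the probe sets kept under other scalings and of splits with genotype means taken out were chosen only after the results were seen, and the counts of other splits were planned.

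The nitrate response differed between genotypes by the test of the difference itself. Against Col-0 it differed in 2 probe sets for nlp6, 60 for nlp7 and 120 for nlp6nlp7, and between nlp6nlp7 and nlp6 in 102. The named genes of the nlp6nlp7 difference were AT1G80380 (-3.68), AT5G01740 (-3.18), AT5G26200 (-2.52), AT5G53750 (-2.19), AT5G52050 (-1.84), AT5G52790 (-1.83), HHO1 (-1.62), AT5G28610 (-1.51), AT1G49000 (-1.51) and AT1G73920 (-1.50). On the higher side they were AT3G14200 (2.35), AT2G47560 (1.49), AT2G19310 (1.22), AT3G13175 (1.17), AT1G53180 (1.12), AT4G08420 (1.03), AT1G76210 (1.03), AT1G11700 (1.02), AT3G13840 (1.02) and AT5G25280 (0.97). For nlp7 they were AT1G80380 (-2.59), AT5G53750 (-2.48), AT5G52050 (-1.95), AT5G26200 (-1.86), AT5G54170 (-1.42), AT4G17670 (1.13), AT1G11700 (1.04), AT4G23870 (0.89), AT2G19310 (0.88) and AT3G16990 (0.80). For nlp6 they were AT4G08420 (1.37) and AT1G77270 (-1.26).

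Lists whose response differed by camera, as median log2 differences, were the nitrate-linked regulators in nlp7 (-0.62) and nlp6nlp7 (-0.37) against Col-0 and in nlp6nlp7 against nlp6 (-0.32), and the glutaredoxins in nlp6nlp7 (-0.62). Plastid-encoded genes differed in nlp6 against Col-0 (0.13) and in nlp6nlp7 against nlp6 (-0.32), and beta-glucosidases in nlp6nlp7 against Col-0 (-0.22). Ribosomal proteins differed in nlp6nlp7 against Col-0 (0.14), nlp7 (0.05) and nlp6 (0.15). Of these 10 calls, only the regulators in nlp7 against Col-0 and in nlp6nlp7 against nlp6 held with an estimated correlation.

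Outside the main measurement, the bacterial control probe set AFFX-r2-Bs-dap-M_at stood 0.65 above Col-0 in nlp7 and 0.69 above it in nlp6nlp7 at 0 min on the log2 scale (limma adjusted p = 0.02 and 0.01 over 62 controls). It also rose by 0.68 in the Col-0 response (adjusted p = 0.012), and its response differed from Col-0 by -1.14 in nlp7 and -0.97 in nlp6nlp7 (adjusted p = 0.0019 and 0.011). The related AFFX-DapX-3_at differed by -0.89 between the nlp6nlp7 and nlp6 responses (adjusted p = 0.012).

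The smaller responses in nlp7 and nlp6nlp7 were weighed against scaling and against a general weakening. Scaling is argued against, since 82 responses were called lower in nlp6nlp7 after quantile normalization, 79 of them among the 88 called as deposited, and 68 after centring, all among the 88. For nlp7, 40 and 48 of the 50 called lower stayed so. A weakening that depends only on a gene's strength of response in Col-0 is argued against for nlp6nlp7, where 98 of 381 probe sets induced in nlp6 (25.7%) departed from a smooth curve, 50 below and 48 above it. For nlp7, 20 of 381 (5.25%) departed at adjusted p under 0.05, 13 below the curve and 7 above it. These argue against such a weakening for those 20 probe sets. Their share is too small to decide for the set as a whole, where it cannot be told apart from a gene-specific loss. Loss of NLP7 function may account for part of the pattern, since 41 of the 50 probe sets lower in nlp7 were also lower in nlp6nlp7, which stays a hypothesis found on these same arrays and in part rests on shared Col-0 arrays.

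For each comparison of 3 against 3 arrays the real split was 1 of 10, too few for a share under 0.05. The real counts and the highest of the other splits were 2306 and 0 for the Col-0 response, 2336 and 2 for nlp6, 1163 and 201 for nlp7, and 1229 and 1 for nlp6nlp7. At 0 min they were 20 and 2 for nlp6, 42 and 1 for nlp7, and 1457 and 0 for nlp6nlp7, and at 35 min 5 and 1, 283 and 1, and 1412 and 0.

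For the response differences 100 splits were drawn, the real one included. As many calls as the 60 in nlp7 came in 3 splits (highest other 65), a share under 0.05. Because these splits mix genotypes, none of their shares is read here as excluding chance. As many as the 2 in nlp6 came in 4 (highest other 2), a share under 0.05, but other splits also gave 2 and the 2 calls were lost in 19 and 20 of 22 alternatives, so they are not secure. As many as the 120 in nlp6nlp7 came in 7 (highest other 347) and as many as the 102 against nlp6 in 8 (highest other 3345), so chance is not excluded by these splits. The other splits mix genotypes, and one with 3345 calls points to the genotype structure of the arrays. With genotype means taken out, the real count was reached in 1 split for nlp7 (highest other 2), 1 for nlp6nlp7 (1) and 1 for nlp6nlp7 against nlp6 (2). Each is a share under 0.05. So is the share for nlp6, reached in 3 with 10 calls in the highest other split, though its 2 calls are not secure. The means taken out were those of the real genotypes, which leaves the real contrast unchanged and alters those of the other splits. The real split is thus not on equal terms with them, and these shares alone do not exclude chance. The counts of 0 for nlp6nlp7 against nlp7 and for additivity were reached in 100 of 100 splits, with highest others of 139 and 1, and of 2 and 24 with means taken out. Any split reaches a count of 0, so those 100 of 100 carry no information.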

How the results depend on the processing

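Leaving out replicate 1 of nlp7 at both times, leaving out the named probe sets of the chromosome 1 run, a replicate block within genotype and every matching of the replicate numbers were chosen only after seeing the data, and the other alternatives were planned. Signal over background limits dim genes: AT4G08420 and AT1G77270, with Col-0 intensities of 20.0 and 6.33 at 0 min, lost their response difference in nlp6 in 19 and 20 of 22 alternatives. The labels do not say that a replicate number marks shared plants or a shared batch. Over all groups, deviations of arrays with the same number had a median correlation across probe sets of 0.011 (84 pairs), against -0.004 with different numbers (168 pairs). Within a genotype, between its 2 times, the medians were 0.102 (12 pairs, -0.008 to 0.469) and -0.061 (24 pairs), and 17 of 24 arrays correlated best with their own number. That is a hint of shared batches within genotypes, strongest in nlp7 (median 0.338), from the data and not the design. Only 6 of the 12 same-number pairs exceeded 0.1, so the group-means model does not pair the arrays. The retained response sets arrays of the same number against each other, a plain matching fixed before the data were examined. A replicate block within genotype gave 0 for the nlp6 difference and 22 for the nlp7 difference, and 110 for the nlp6nlp7 difference against 120.

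In size, 21 of 81 single-gene values moved by over 1.5 times, all with a pseudocount of 3 or 103 and 0 in any other setting. For single genes 1323 values under the alternatives kept their direction and side of the threshold, 304 kept their direction and lost the call, and 0 reversed. For lists 1642 stayed, 20 gained a call, 104 lost it and 3 reversed, judged by the direction of the camera test. These were the plastid-encoded genes in the nlp7 response without replicate 1 of nlp7 at 0 min (median -0.01, from -0.27 with all arrays, so the median itself did not change sign; adjusted p = 0.985), ribosomal proteins in the nlp6nlp7 against nlp7 difference without replicate 1 of nlp7 at 35 min (-0.01, from 0.05; adjusted p = 0.95), and ribosomal proteins in nlp6nlp7 at 0 min after quantile normalization (0.02, from -0.05; adjusted p = 0.808). Over all single arrays left out, the first of these medians ranged from -0.41 to -0.01 and the next from -0.01 to 0.15. The cause was not tested for these or for the counts that follow, except where fewer probe sets or arrays entered by construction.

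With 1 probe set per named gene, fewer probe sets were tested and the responses called 1118 in Col-0, 1143 in nlp6, 531 in nlp7 and 596 in nlp6nlp7. The differences called 21 in nlp7, 49 in nlp6nlp7 and 41 against nlp6, the 0 min comparisons 20 in nlp7 and 730 in nlp6nlp7, and the 35 min comparisons 3, 112 and 685. With only the arrays compared, fewer arrays set the variance. The calls were 1230 and 408 for the nlp6 and nlp7 responses, 9 for the nlp7 difference, 58 against nlp6, 0 and 1 for nlp6 and nlp7 at 0 min, and 0 and 25 at 35 min.

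Array weights gave 2082 for the nlp6nlp7 response, 0 and 278 for the nlp6 and nlp6nlp7 differences, 110, 25 and 2968 for nlp6, nlp7 and nlp6nlp7 at 0 min, and 3, 582 and 2251 at 35 min. The replicate block gave 0 for the nlp6 difference, 1 for nlp6nlp7 against nlp7 and 36 for nlp6 at 0 min. Without the dimmest 50% the calls were 0 for the nlp6 difference, 2 for nlp6nlp7 against nlp7, 67 and 83 for nlp6 and nlp7 at 0 min, and 16 and 441 at 35 min. Trended robust variances gave 0, 4 for nlp6nlp7 against nlp7, 78 for nlp7 at 0 min and 10 for nlp6 at 35 min. The 5th percentile pseudocount gave 0 for the nlp6 difference, 24 for nlp7 at 0 min and 0 for nlp6 at 35 min, and the 40th gave 0, 2 for nlp6nlp7 against nlp7 and 17 for nlp6 at 35 min. The nlp6 difference also called 1 after quantile normalization and 0 after centring or without the dimmest 25%, and nlp6 at 0 min called 32 after quantile normalization. Without replicate 1 of nlp7 at both times the nlp7 difference called 26 and nlp7 at 0 min 11.

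Leaving out 1 array at a time, the lowest and highest counts were 0 and 1 for the nlp6 difference, 28 and 59 for nlp7, 70 and 114 for nlp6nlp7, and 0 and 1 for additivity. At 0 min they were 2 and 49 for nlp6, 8 and 119 for nlp7 and 804 and 1014 for nlp6nlp7, and at 35 min 1 and 62, 114 and 228, and 907 and 1148. For the responses, which all stayed within 1.5 times, they were 1730 and 2000 in Col-0, 1836 and 2197 in nlp6, 855 and 1118 in nlp7, and 860 and 1022 in nlp6nlp7.

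Over all 216 matchings of the replicate numbers, the retained share of lowered genes lay between 71.5% and 79.5% in nlp7 (p from 0.1 to 0.3) and between 67.4% and 73.3% in nlp6nlp7, and the mean of each share stayed within its SD by number. The share of induced response retained in nlp6nlp7 was 68.2% after quantile normalization, 57.3% with no fold minimum and 74.9% with a 4-fold minimum. The share of lowered response retained in nlp6 was 94.0% after centring, 94.5% with the 40th percentile pseudocount, 94.9% with no fold minimum and 90.1% with a 4-fold minimum.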

Other observations

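The tests of the chromosome 1 run were chosen only after the result was seen.

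A candidate explanation for the run from AT1G20910 to AT1G27530 is extra copies of that stretch in the nlp6nlp7 line, which would raise its genes by a like factor at both times. The interquartile range of log2 differences, averaged over both times, was 0.25 in the run and 0.23 outside, a ratio of 1.09, and all 155 genes were higher at 35 min too, though not all evenly: HHO3 was 0.64 higher at 0 min and 0.27 at 35 min, and the dimmer SWEET1 0.59 and 0.22. The authors' scaling is argued against, since the run's median was still 0.74 after centring. A stretch from another accession would lower the signal of many Col-0 probes, and 0 of 155 genes were lower. Of all 316 named probe sets of the run, 189 were called higher and 0 lower at 0 min. The run was chosen by its shared rise at 0 min, which favours such counts, so they argue against another accession only weakly. Joint regulation by loss of NLP6 and NLP7 cannot be told apart from extra copies by expression alone, because the median of -0.02 in nlp6 at 0 min says nothing about the loss of both. Measuring DNA copy number in the line, which was not analysed here, would separate them.

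By brightness, the run's median over both times was 0.87 in the dimmest 51 genes, 0.92 in the middle 52 and 0.77 in the brightest 52. In the whole run it was 0.85, or 1.80-fold.

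Replicate 1 of nlp7 stood apart at both times. Its deviations from the group mean at 0 min and 35 min correlated across 22714 probe sets (r = 0.47; probe sets are not independent replicates), 356 of them deviated by more than 0.5 on the log2 scale in the same direction at both times, and its array weights were 0.408 and 0.477, the lowest of the 24. The labels do not say what the replicates of different times share.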
